A study of Homo sapiens and Mus musculus with 37 samples.

How the data were processed

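The series measured RNA on Affymetrix Gene 1.0 ST arrays, with 29 human arrays in 10 groups and 8 mouse arrays in 3 groups. Per the labels, cells were infected with retrovirus, sorted by flow cytometry, and lysed for RNA with a column kit, and 2 to 5 ng of total RNA was amplified and biotinylated for each array. The deposited values are log2 probe set summaries from RMA, and the submitters' processing notes name Affymetrix Power Tools 1.12.0. The authors' values lie on a common scale between arrays. Whether all arrays were normalized together, and with which filters, is not stated. The array medians lay close together within each species, and the values were used as deposited, with no further normalization, background correction or filter on dim genes. For arrays, the number of arrays per group limits the precision.

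The human table had 25127 rows, of which 3324 (13.2%) were blank in every array. Of the 21803 human rows with values, 16978 were paired by the platform's probe table with exactly 1 gene symbol, 1406 with several symbols and 3419 with none. The mouse table had 28815 rows, 293 of them blank, and 21681 rows with exactly 1 symbol. Rows with several symbols or none were left out of the gene tests, and 56 human and 91 mouse rows of genes that reveal sex were removed before any test. In 443 human and 993 mouse symbols, several rows shared the symbol, and the row with the highest mean over all arrays of that table was kept. This left 16387 human and 19838 mouse genes. Genes are named by the symbol in the probe table. The table of values gives no genome positions, so none are printed. The probes do not separate a delivered transcript from the cell's own transcript.

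Groups were taken from titles, source names and cell types. The H9F line is labelled as cardiac fibroblasts; per the study it derives from the H9 embryonic stem cell line. HDF are dermal fibroblasts. The labels call reprogrammed cells iCM and give the number of factors (5F or 7F) and, for some groups, a time (4W or 12W), read here as weeks. The H9F iCM groups without 12W carry no time in their labels. They are called earlier here, an order that was assumed. The labels do not name the factors. The names used here (GATA4, MEF2C, TBX5, ESRRG and MESP1 for 5 factors, with MYOCD and ZFPM2 added for 7) come from knowledge of the study and not from the labels. The factors delivered to the mouse cells are not known from the labels. One array carried the dermal fibroblast group code but a reprogrammed title, source name and cell type, and its title held no replicate number. It was placed by its title as HDF_iCM_7F_4W replicate 3. No label says whether replicates are separate cultures or donors, so the p-values measure the spread between arrays and no more.

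For each species, limma 3.58.1 in R 4.3.3 fitted one linear model with a mean per group to the log2 values, with empirical Bayes variances and no replicate block. Each comparison was a contrast of group means with its standard error (SE), and p-values were adjusted by the Benjamini-Hochberg method over all genes of that comparison. A gene was called higher (rose) or lower (fell) at an adjusted p under 0.05 and an absolute log2 change of at least 1, a fold of 2. Because all human groups share the variance of a gene, an array that stands apart in one group widens the errors in every human comparison. There were 25 comparisons, 2 of them interactions that test whether a change differs between times and factor sets or between fibroblast sources.

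The 25 gene lists, the comparisons, their tests and the rule for naming genes were fixed before the data were examined. The tests for a mixture and for leukocytes, the steroid-enzyme genes and GNG8 were chosen later. The lists were sarcomere, calcium handling, cardiac ion channels, cardiac secreted and chamber genes, cardiac transcription factors not delivered, delivered factors, fatty acid oxidation and cardiac energy metabolism, oxidative phosphorylation, fibroblast and matrix, smooth muscle, skeletal muscle, cell cycle, interferon response, inflammatory secretion, p53 targets, unfolded protein and integrated stress response, cholesterol synthesis, and markers of endothelial, leukocyte, erythroid, pluripotent, endoderm and liver, epicardial, neural and keratinocyte cells. For each list, called members were counted, first with p-values adjusted over all genes and again adjusted over the list alone. limma's camera compared each list with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and was repeated with the correlation estimated from the data. Named genes were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, up to 4 members of each described list with the largest changes and any exception, and a core panel with the delivered factors whatever their result (TNNT2, MYH6, MYH7, ACTC1, NPPA, NPPB, RYR2, PLN, TNNI3, MYL7, COL1A1, COL1A2, THY1 and POSTN). Human TNNT2 had no usable row.

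The position of an array between fibroblasts and cardiomyocytes was the least squares slope through the origin, across genes called between those 2 reference groups, of the array's difference from the fibroblast mean on the cardiomyocyte difference from the fibroblast mean. It is 0 at the fibroblast mean and 1 at the cardiomyocyte mean. Delivered factors were left out of it. Groups were compared by exact two-sided permutation tests of the mean. Reference genes moved are the cardiomyocyte-high genes that rose, and the fibroblast-high genes that fell, in a reprogrammed group. Both measures use the starting fibroblasts on either side, so their values for unchanged groups were simulated 100 times. Each simulation drew the residuals of whole arrays with replacement. The human simulations left out the 2 dermal arrays that stood apart from their groups. The limma tests and the position were also tested on simulated data with known changes. With changes of 1.5, 2, 3 and 5 log2 units the share recovered was 84%, 90%, 98% and 100% for 7-factor H9F cells against H9F fibroblasts, 58%, 86%, 98% and 100% for 12W dermal cells against HDF, and 56%, 80%, 96% and 98% for mouse iCMs against fibroblasts. In those tests 13, 4 and 10 unchanged genes were called, and a simulated position of 0.4 was recovered as 0.410. The changed genes were drawn at random and the noise was independent between genes. The shares therefore need not hold for genes whose errors the 2 dermal arrays widen.

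Alternatives planned for the counts of genes were only the arrays of the groups compared, a replicate block, quantile normalization, centring each array on its median, leaving out dim genes, a trended and robust variance prior, array weights, every row of the table, and leaving out each replicate of the compared groups and the array with the conflicting group code. Alternatives for positions, reference genes, lists and named genes are given with their values. By the rule used, replicate numbers did not pair arrays across groups. In 0 of 45 pairs of human groups and 0 of 3 pairs of mouse groups was every correlation between same-numbered arrays over 0.1. The replicate block therefore serves as an alternative. Between the earlier 7-factor and 5-factor H9F iCMs these correlations of deviations from group means ran from −0.0166 to 0.294. Arrays with other numbers had a mean of −0.0922, so some pairing there stays open. The human block fits also left out HDF_iCM_7F_4W replicate 3. Leaving out the 2 dermal arrays that stood apart from their groups was chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Nothing was left out of the human or mouse samples.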

Results

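RNA from human and mouse cells was measured on whole-transcript arrays to ask how far reprogrammed fibroblasts had come to resemble cardiomyocytes. The 29 human arrays comprised H9F fibroblasts, HDF dermal fibroblasts, cardiomyocytes derived from the H9 embryonic stem cell line, fetal cardiomyocytes, and 6 groups of reprogrammed cells, called iCMs in the labels. H9F iCMs had received 5 or 7 factors. They were collected at 12W or at a time that the labels do not give, assumed here to be earlier. HDF iCMs had received 7 factors and were collected at 4W or 12W. Every human group held 3 arrays except the 12W HDF iCMs, which held 2. The 8 mouse arrays comprised 3 of cardiomyocytes, 2 of iCMs and 3 of cardiac fibroblasts. The number of arrays limits the precision of every value. Values are log2 signals, changes are differences of group means with their standard errors, and p-values are from limma adjusted over all genes unless a list is named. In each named gene called with all arrays, every array of one group lay beyond every array of the other.

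A pair of dermal arrays stood apart from the groups their labels give. Across genes, the library labelled HDF replicate 3 correlated best with HDF iCM 4W replicate 1 (r = 0.975) and at most at 0.888 with the other HDF arrays. The library labelled HDF iCM 4W replicate 3 correlated best with HDF replicate 1 (r = 0.973) and at most at 0.887 with its own group; it also carried the fibroblast group code in its labels. MYOCD, a cardiac and smooth muscle co-activator, was 7.69 log2 units above the other HDF arrays in the first and −8.66 from the other 4W iCM arrays in the second. Both were kept as labelled, and the dermal results are also given without them. H9F fibroblast replicate 1 also stood apart from its group, with correlations of 0.852 to 0.886 with the other arrays.

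**Figure D1:**
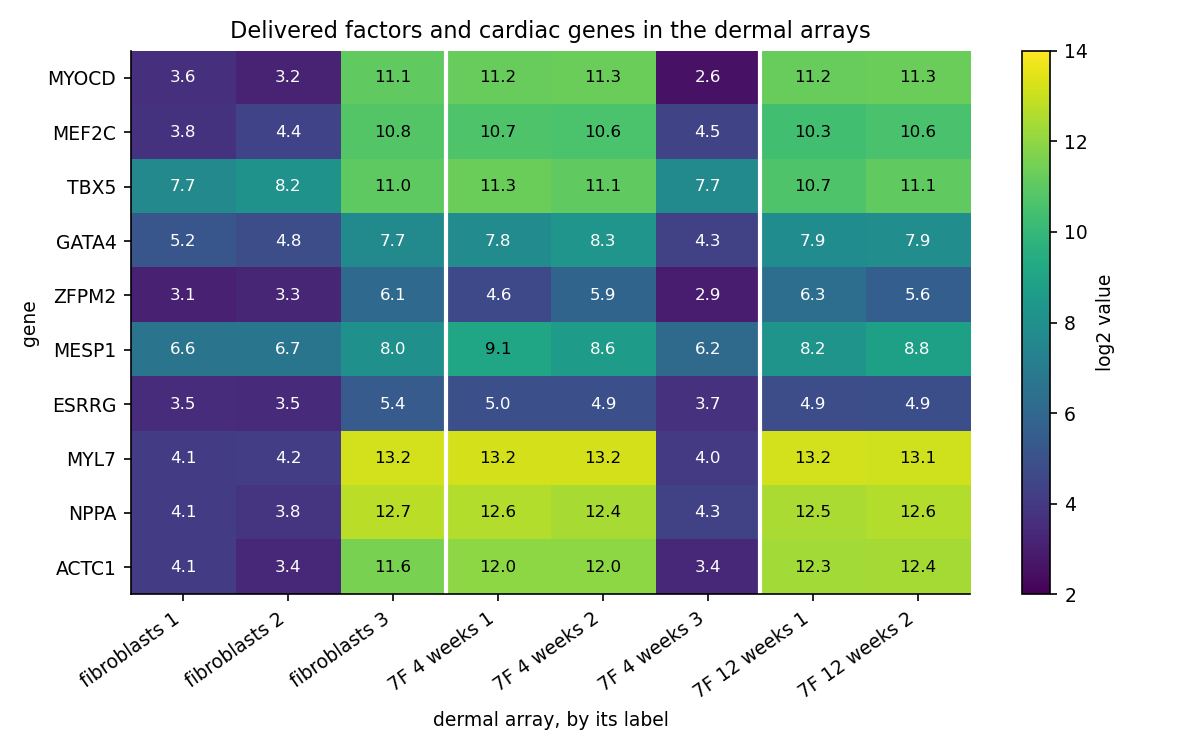
Heat map of log2 signal for the 7 delivered factors and the cardiac genes MYL7, NPPA and ACTC1 (vertical axis) in the 8 dermal arrays (horizontal axis), with each value printed in its cell. The library labelled HDF replicate 3 shows high signals and the library labelled HDF iCM 4W replicate 3 low ones, unlike the other arrays of their groups.

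The first comparison, H9 cardiomyocytes against H9F fibroblasts (n = 3 and 3), set the ends of the scale on which reprogramming was measured. The contractile genes MYL7, an atrial myosin light chain, and ACTC1, cardiac actin, were 9.33 ± 1.78 and 8.69 ± 1.63 log2 units higher in cardiomyocytes (adjusted p = 0.00041 and 0.00033), and TECRL, a cardiac gene linked to inherited arrhythmia, was 8.32 ± 0.45 higher (adjusted p = 2.08e-12). Of 30 measured sarcomere genes, 25 were higher (27 adjusted over the list alone), including MYH6 by 7.42 ± 1.17 and MYH7 by 6.31 ± 0.48, the main cardiac myosin heavy chains. Of 18 calcium handling genes 12 were higher (14 over the list alone), with the release channel RYR2 up by 6.45 ± 0.48 and PLN, which restrains calcium uptake, by 7.06 ± 1.20. Of 18 cardiac transcription factors outside the delivered set, 12 were higher, such as TBX20 (5.18 ± 0.47) and NKX2-5 (2.68 ± 0.22). Of 35 fibroblast and matrix genes 23 were lower (25 over the list alone), including COL1A1 (−2.90 ± 0.46), COL1A2 (−4.09 ± 0.49), THY1 (−4.01 ± 0.87) and POSTN (−4.69 ± 0.84). In all, 1364 genes were higher and 1313 lower in cardiomyocytes.

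Camera adjusted p-values for this comparison were 4.13e-28 for sarcomere (median log2 change 6.10), 1.32e-13 for calcium handling (2.25), 2.25e-12 for the transcription factors (1.78), 2.08e-15 for fatty acid oxidation and cardiac energy metabolism (20 of 31 higher, 1.65) and 2.08e-15 for fibroblast and matrix (−2.35), and these calls held with an estimated correlation, as did that of cardiac secreted and chamber genes (7 of 10 higher, 1 lower, adjusted p = 2.11e-05). Other calls were lost with it. Cell cycle genes (25 of 35 higher, adjusted p = 3.39e-15) had an adjusted p = 0.0736 with an estimated correlation, and oxidative phosphorylation (7 of 26 higher, adjusted p = 2.32e-06) 0.24. With it, cholesterol synthesis (8 of 14 higher, adjusted p = 2.32e-06) had 0.11, cardiac ion channels (5 of 15 higher, 1 lower, adjusted p = 0.003) 0.13, delivered factors (4 of 7 higher, adjusted p = 0.00143) 0.24, and endoderm and liver markers (7 of 10 higher, adjusted p = 7.99e-05) 0.182. Lower lists that lost their calls were interferon response (6 of 26 lower, 1 higher, adjusted p = 0.00762), inflammatory secretion (4 of 18 lower, adjusted p = 0.00199), p53 targets (4 of 12 lower, 1 higher, adjusted p = 0.0196) and the unfolded protein and integrated stress response (9 of 19 lower, 1 higher, adjusted p = 0.0044), with adjusted p = 0.154, 0.18, 0.11 and 0.0736 with an estimated correlation. Other lists had no call. These were smooth muscle (4 of 13 higher, 3 lower, adjusted p = 0.467) and skeletal muscle (1 of 17 higher, adjusted p = 0.626). The same held for endothelial markers (1 of 11 higher, 1 lower, adjusted p = 0.947), leukocyte markers (0 of 11, adjusted p = 0.384) and erythroid markers (0 of 6, adjusted p = 0.823). It also held for pluripotent markers (1 of 5 lower, adjusted p = 0.697), epicardial markers (2 of 9 higher, 1 lower, adjusted p = 0.766; median −0.26, mean 0.07), neural markers (1 of 9 higher, 1 lower, adjusted p = 0.626) and keratinocyte markers (0 of 7, adjusted p = 0.823). Over the 25 comparisons, 59 of 244 camera calls held with an estimated correlation.

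Fetal cardiomyocytes served as a second reference. Against H9F fibroblasts (n = 3 and 3), the ventricular light chain MYL2 was higher by 7.95 ± 0.78 (adjusted p = 3.95e-08), MYH7 by 7.77 ± 0.48 (adjusted p = 1.6e-11), and the calcium store protein CASQ2 by 8.50 ± 0.68 (adjusted p = 1.42e-09). Of 30 sarcomere genes 26 were higher (28 over the list alone), camera adjusted p = 2.23e-29, and of 35 cell cycle genes 33 were higher, adjusted p = 2.17e-28. Genes of other cell types were also higher, among them CDH5 of endothelium (4.62 ± 0.23), FCER1G of myeloid cells (2.41 ± 0.29) and the globin HBB (5.84 ± 0.35). Of 11 endothelial markers 9 were higher (adjusted p = 3.42e-12), of 11 leukocyte markers 4 (adjusted p = 0.000559; adjusted p = 0.0533 with an estimated correlation) and of 6 erythroid markers 4 (adjusted p = 1.08e-05). Only 2 of 35 fibroblast and matrix genes were higher and 7 lower (adjusted p = 0.301). In all 1534 genes were higher and 1351 lower, and the median over all genes was −0.13.

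H9 cardiomyocytes were then set against fetal cardiomyocytes (n = 3 and 3) to see how the references differ. MYH6 was 4.32 ± 1.17 higher in H9 cardiomyocytes (adjusted p = 0.0143), whereas CASQ2 (−6.69 ± 0.68), the intermediate filament gene DES (−4.02 ± 0.62) and the fatty acid transporter CD36 (−6.17 ± 0.76) were lower. MYL7, ACTC1, NPPA and RYR2 did not differ past the threshold (adjusted p = 0.976, 0.991, 0.885 and 0.468), which does not show equal levels. Of 35 fibroblast and matrix genes 21 were lower in H9 cardiomyocytes (adjusted p = 1.78e-16), and of 11 endothelial markers 9 were lower (adjusted p = 4.64e-18). Cholesterol synthesis genes were higher, 7 of 14 (8 over the list alone; adjusted p = 4.44e-08; adjusted p = 0.0744 with an estimated correlation), such as SQLE by 2.14 ± 0.29. In all 562 genes were higher and 872 lower.

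The starting fibroblasts were compared to show what the sources brought with them (HDF against H9F fibroblasts, n = 3 and 3). HDF had more TBX5, a cardiac and limb transcription factor that is also a delivered factor, by 4.62 ± 0.71 (adjusted p = 0.000216), more CTSK, a matrix-degrading protease, by 4.76 ± 0.37, and less POSTN by −4.52 ± 0.84 and KRT8, an epithelial keratin, by −4.78 ± 0.50. Of 12 p53 targets 5 were higher in HDF (6 over the list alone), with camera adjusted p = 4.87e-08, a call that held with an estimated correlation. Sarcomere genes had a camera adjusted p = 0.00367 (median 0.88, 1 of 30 higher; adjusted p = 0.758 with an estimated correlation). Without the 2 arrays out of place the sarcomere adjusted p was 0.702 and the median −0.01. In all 318 genes were higher and 364 lower. Without the 2 arrays 472 were higher and 456 lower, with 533 of the 682 calls shared. TBX5 was then higher by 3.59, CTSK by 4.76 ± 0.41, and POSTN and KRT8 were lower by −5.59 and −4.57.

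With 5 factors at the earlier time, H9F iCMs had switched on many cardiac genes (n = 3, against 3 H9F fibroblast arrays). MYL7 rose by 8.92 ± 1.78 (from 3.80 to 12.72; adjusted p = 0.00203), the natriuretic peptide gene NPPA by 7.40 ± 1.67 (adjusted p = 0.00482), NPPB by 7.25 ± 1.73, ACTC1 by 7.28 ± 1.63, and TNNI3, cardiac troponin I, by 7.12 ± 0.96 (adjusted p = 3.3e-05). The muscle LIM protein gene CSRP3 rose by 7.63 ± 0.61 (adjusted p = 2.67e-08). MYH6, PLN and RYR2 rose by 4.22 ± 1.17, 4.32 ± 1.20 and 2.01 ± 0.48. These calls ended when 1 array was left out: MYH6 without H9F fibroblast replicate 3 (3.86) or iCM replicate 1 (4.02), PLN without iCM replicate 1 (4.03) or 3 (4.18), and RYR2 without iCM replicate 1 (1.63). MYH7 did not pass (0.83 ± 0.48, adjusted p = 0.302). The fibroblast core genes COL1A1, COL1A2, THY1 and POSTN did not pass either, at −0.77, −0.84, −0.71 and 0.86, and without fibroblast replicate 2 COL1A2 passed at −1.49; among falls were the pentraxin PTX3 (−4.40 ± 0.86) and the PDGF receptor PDGFRB (−3.39 ± 0.84). Of the delivered factors, TBX5 rose by 6.68 ± 0.71, MEF2C by 5.81 ± 1.30, MESP1 by 2.42 ± 0.50 and ESRRG by 1.62 ± 0.45, the last not past the threshold without any of 5 single arrays (1.48 to 1.66). GATA4 stood at 1.93 ± 0.70 (adjusted p = 0.0753), and it passed without HDF iCM 4W replicate 3. Neither of the factors that these cells did not receive passed: MYOCD at 1.75 ± 1.69 (adjusted p = 0.591) and ZFPM2 at −1.09 ± 0.67 (adjusted p = 0.339). In all 986 genes rose and 417 fell.

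By list, 17 of 30 sarcomere genes rose with 5 factors (18 over the list alone), median 1.69, camera adjusted p = 3.96e-11 (adjusted p = 0.445 with an estimated correlation). Fatty acid oxidation and energy genes rose in 13 of 31 (15 over the list alone; adjusted p = 1.08e-09), with ACADM, a fatty acid dehydrogenase, up by 2.52 ± 0.42, and oxidative phosphorylation genes in 9 of 26 (adjusted p = 5.48e-13), each with adjusted p = 0.425 with an estimated correlation. Calcium handling genes rose in 4 of 18 (5 over the list alone; adjusted p = 0.0845) and cardiac transcription factors in 3 of 18 (adjusted p = 0.12). Of 35 fibroblast and matrix genes 8 fell (adjusted p = 3.66e-05; adjusted p = 0.495 with an estimated correlation). Of 35 cell cycle genes 10 rose (13 over the list alone; adjusted p = 1.69e-08; adjusted p = 0.445 with an estimated correlation).

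With 7 factors at the earlier time (n = 3, against the same 3 H9F fibroblast arrays), MYL7, NPPA and ACTC1 rose by 9.24 ± 1.78, 8.28 ± 1.67 and 8.16 ± 1.63, and MYH6 by 6.06 ± 1.17 (adjusted p = 0.00103). MYH7 rose by 2.96 ± 0.48 (adjusted p = 0.000188), PLN by 5.15 ± 1.20 and RYR2 by 2.27 ± 0.48. The added factor MYOCD rose by 7.40 ± 1.69 (adjusted p = 0.00447), while ZFPM2 stood at 1.37 ± 0.67 (adjusted p = 0.178), GATA4 at 1.82 ± 0.70 (adjusted p = 0.0833) and ESRRG at 1.15 ± 0.45 (adjusted p = 0.0879); GATA4 passed without HDF iCM 4W replicate 3. TBX5, MEF2C and MESP1 rose by 6.69 ± 0.71, 5.76 ± 1.30 and 2.14 ± 0.50. COL1A1 fell by 2.26 ± 0.46 and PTX3 by 5.51 ± 0.86. COL1A2 and THY1 fell by 1.93 ± 0.49 and 3.10 ± 0.87. The COL1A2 call ended without fibroblast replicate 3 (−1.34) or iCM replicate 2 (−1.62). The THY1 call ended without fibroblast replicate 2 (−2.28) or 3 (−2.86) or iCM replicate 1 (−2.93) or 3 (−2.87). POSTN was not called (−1.60 ± 0.84, adjusted p = 0.216). In all 1204 genes rose and 553 fell.

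Of the lists, sarcomere rose in 19 of 30 with 7 factors (median 2.95, camera adjusted p = 2.55e-14) and fatty acid oxidation and energy genes in 12 of 31 (17 over the list alone; adjusted p = 7.01e-09), each with adjusted p = 0.185 with an estimated correlation. Of 35 fibroblast and matrix genes 19 fell and 1 rose, S100A4 (1.74 ± 0.32), with adjusted p = 4.23e-10 and 0.185 with an estimated correlation. Smooth muscle genes rose in 5 of 13 (adjusted p = 4.78e-05; adjusted p = 0.316 with an estimated correlation), such as ACTA2, smooth muscle actin, by 5.11 ± 0.69. Interferon response genes rose in 13 of 26 (14 over the list alone) and fell in 1, MX2; the antiviral genes MX1 and IFIT1 rose by 4.08 ± 0.41 and 3.36 ± 0.41. The interferon list had adjusted p = 3.94e-09 and was the 1 list of 11 called that held with an estimated correlation. The skeletal muscle list had a median of −0.03 and a mean of 0.81.

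At 12W, H9F iCMs with 5 factors (n = 3, against the same fibroblasts) kept high MYL7 (9.05 ± 1.78), NPPA (8.15 ± 1.67) and TNNI3 (7.56 ± 0.96), and MYH7, RYR2 and PLN rose by 1.88 ± 0.48, 3.12 ± 0.48 and 6.42 ± 1.20. COL1A1, COL1A2, POSTN and THY1 all fell, by 2.00 ± 0.46, 2.20 ± 0.49, 3.87 ± 0.84 and 4.20 ± 0.87. Of 35 fibroblast and matrix genes 24 fell (25 over the list alone; camera adjusted p = 1.24e-15), of 26 oxidative phosphorylation genes 23 rose (median 1.38, adjusted p = 1.8e-22), and of 31 fatty acid oxidation and energy genes 17 rose (19 over the list alone; adjusted p = 8.18e-14); each of these had adjusted p = 0.0594 with an estimated correlation. Sarcomere genes rose in 16 of 30 (19 over the list alone; adjusted p = 8.18e-14; adjusted p = 0.176 with an estimated correlation). Among delivered factors TBX5, MEF2C and MESP1 rose by 6.48 ± 0.71, 5.35 ± 1.30 and 1.82 ± 0.50. ESRRG, at 1.28 ± 0.45, was called with all arrays (adjusted p = 0.0464) and not without any of 5 single arrays (1.14 to 1.29), and GATA4 stood at 1.85 ± 0.70 (adjusted p = 0.0682) and passed without HDF iCM 4W replicate 3. In all 1297 genes rose and 862 fell.

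With 7 factors at 12W (n = 3, against the same fibroblasts), MYL7, NPPA and ACTC1 rose by 9.24 ± 1.78, 8.46 ± 1.67 and 7.99 ± 1.63, MYH6 by 6.60 ± 1.17 and MYH7 by 4.29 ± 0.48 (adjusted p = 3.17e-06). MYL3, a ventricular myosin light chain, rose by 3.58 ± 0.47, RYR2 by 3.45 ± 0.48 and PLN by 7.00 ± 1.20. Of 30 sarcomere genes 24 rose (25 over the list alone; median 3.96, adjusted p = 1.75e-25), of 18 calcium handling genes 11 rose (median 1.41, adjusted p = 1.66e-08), of 31 fatty acid oxidation and energy genes 21 rose (23 over the list alone) and of 26 oxidative phosphorylation genes 18 rose (adjusted p = 2.27e-23). Of 35 fibroblast and matrix genes 23 fell and 1 rose (adjusted p = 1e-15), with COL1A1, COL1A2, THY1 and POSTN down by −2.33 ± 0.46, −2.14 ± 0.49, −4.10 ± 0.87 and −3.66 ± 0.84. These 5 list calls held with an estimated correlation. MYOCD, TBX5 and MEF2C rose by 6.69 ± 1.69, 6.08 ± 0.71 and 5.25 ± 1.30; MESP1 rose by 1.45 ± 0.50, a call that ended without fibroblast replicate 2 (1.32) or 3 (1.41) or iCM replicate 2 (1.06) or 3 (1.54). GATA4 (2.83-fold, adjusted p = 0.153), ESRRG (1.14 ± 0.45, adjusted p = 0.0828) and ZFPM2 (1.40 ± 0.67, adjusted p = 0.163) were not called, though GATA4 passed without HDF iCM 4W replicate 3. In all 1096 genes rose and 872 fell.

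**Figure D2:**
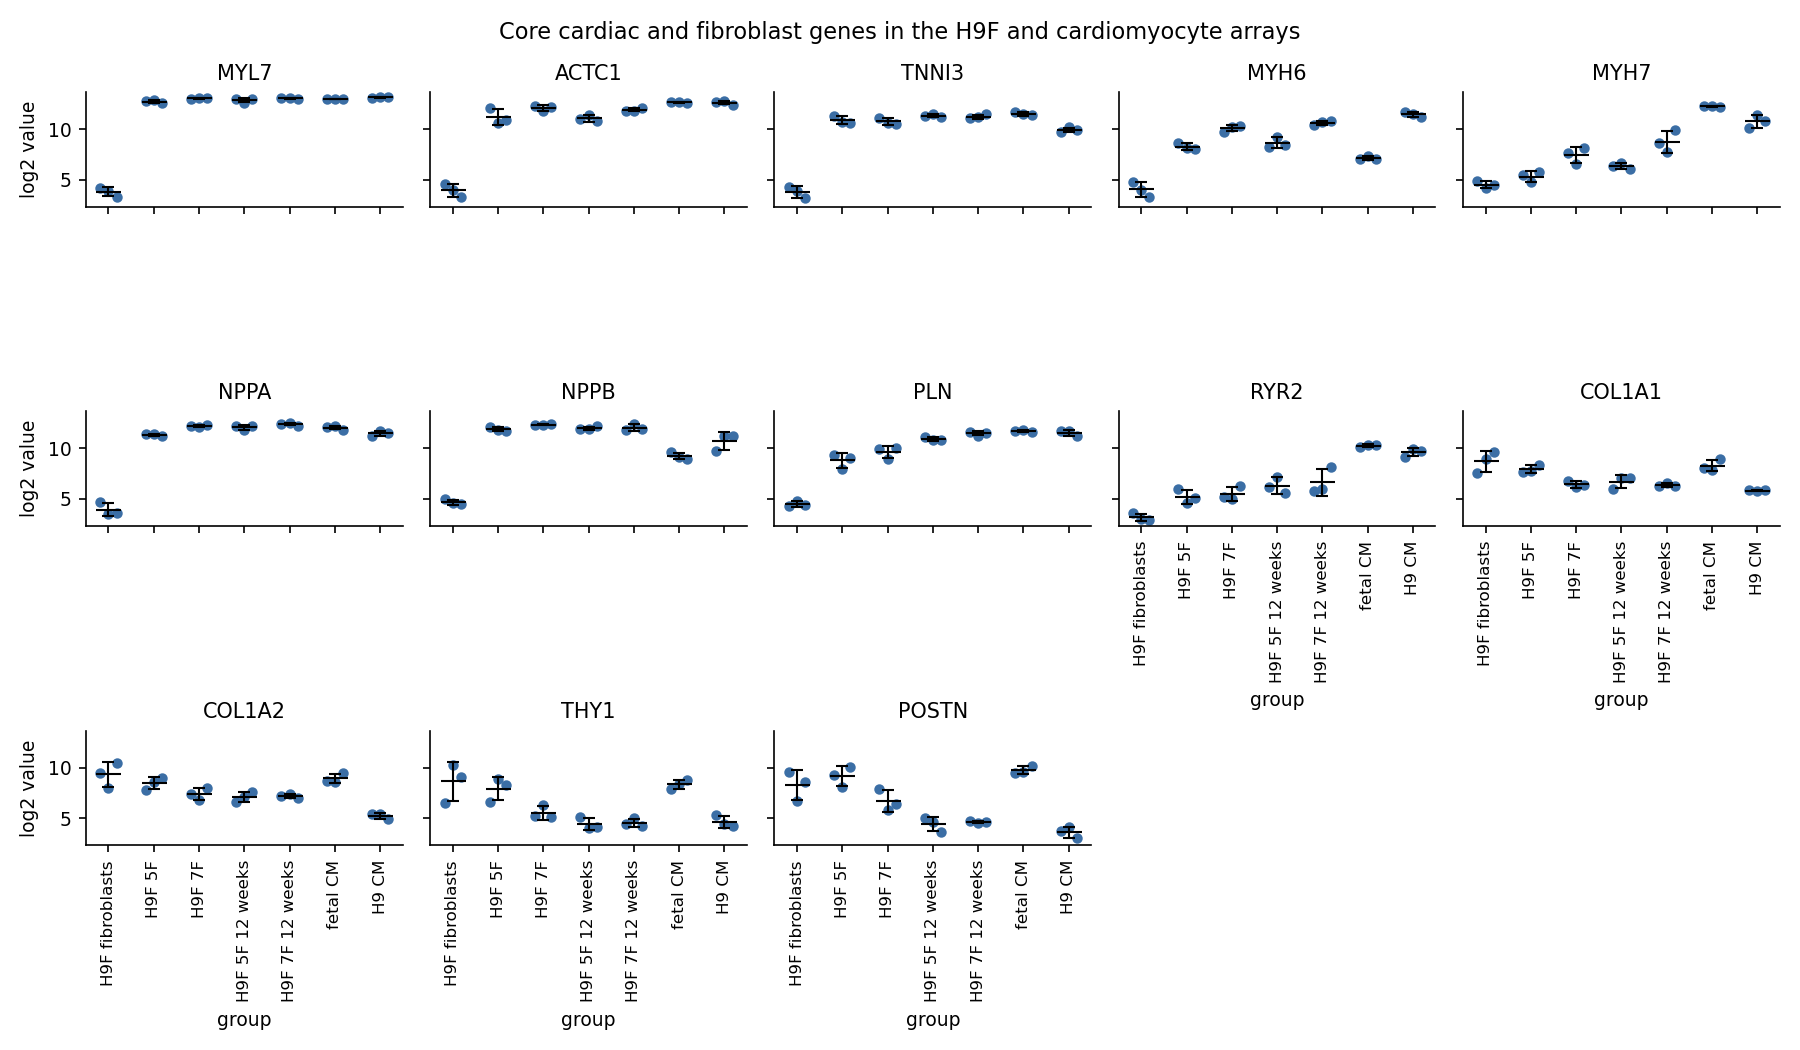
Log2 signal (vertical axis) of the core cardiac and fibroblast genes in each array of 7 human groups (horizontal axis), with points for arrays and bars for mean and SD. MYL7, NPPA and ACTC1 are high in all 4 groups of H9F iCMs, while MYH7 and RYR2 lie below H9 cardiomyocytes.

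Whether the added factors changed the cells was asked by comparing 7 with 5 factors (n = 3 and 3 at each time). At the earlier time 13 genes were higher and 3 lower with 7 factors. The antiviral genes MX1 and OAS1 were higher by 2.98 ± 0.41 and 2.19 ± 0.30 (adjusted p = 0.00171 for both), HP, haptoglobin, by 5.14 ± 0.84 (adjusted p = 0.00727), TNNI1, slow skeletal and fetal cardiac troponin I, by 2.88 ± 0.45, and S100A4 by 1.99 ± 0.32. Without iCM 7-factor replicate 3 HP (4.79), TNNI1 (2.89) and S100A4 (1.89) lost their calls, as did HP without 5-factor replicate 2 (4.32) and S100A4 without 5-factor replicate 1 (1.80). The added factors themselves did not pass: MYOCD was at 5.65 ± 1.69 (adjusted p = 0.65) and ZFPM2 at 2.46 ± 0.67 (adjusted p = 0.398), and MYH7 was at 2.13 ± 0.48 (adjusted p = 0.132), passing without 7-factor replicate 2 (2.59). Without the 2 dermal arrays out of place, whose spread enters every human error, all 3 passed: MYOCD by 5.65 ± 0.58 (adjusted p = 5.69e-06), ZFPM2 by 2.46 ± 0.43 (adjusted p = 0.0064) and MYH7 by 2.13 ± 0.45 (adjusted p = 0.0344), among 46 genes. Of 26 interferon genes 5 were higher (12 over the list alone; median 0.98, camera adjusted p = 6.81e-29), a call that held with an estimated correlation. Smooth muscle (median 0.98, adjusted p = 2e-09, 2 over the list alone) and fibroblast and matrix (median −0.68, adjusted p = 1.75e-09) did not hold, each with adjusted p = 0.254 with an estimated correlation. The delivered factor list had a median of −0.05 and a mean of 1.03 (adjusted p = 0.165). The count of 16 became 9, 8 and 8 without 5-factor replicates 1, 2 and 3, and 2 without 7-factor replicate 3.

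At 12W, 4 genes were higher and 1 lower with 7 than with 5 factors. MYL3 was higher by 3.47 ± 0.47 (adjusted p = 0.00087), and the smooth muscle genes MYLK, myosin light chain kinase, and TPM2, a tropomyosin, by 2.46 ± 0.30 and 1.72 ± 0.22. DSC1, a desmosome gene, was 1.72 ± 0.31 higher and CDO1, which oxidises cysteine, −1.58 ± 0.28; each lost its call without any of 4 single arrays (1.56 to 1.64, and −1.53 to −1.31). MYOCD stood at 5.71 ± 1.69 (adjusted p = 0.593) and passed without the 2 dermal arrays (5.71 ± 0.58, adjusted p = 6.18e-06), as did MYH6 (2.00 ± 0.30), MYH7 (2.41 ± 0.45) and ZFPM2 (2.39 ± 0.43), among 42 genes. Smooth muscle genes had 2 of 13 higher (3 over the list alone; median 1.71, camera adjusted p = 8.73e-18; adjusted p = 0.0605 with an estimated correlation), and sarcomere genes 1 of 30 (5 over the list alone; adjusted p = 9.39e-14; adjusted p = 0.216 with an estimated correlation). The interferon median was 0.01. The count of 5 became 3 without 5-factor replicate 3 or 7-factor replicate 1, 16 without HDF iCM 4W replicate 3 and 25 without 7-factor replicate 2. Reprogrammed groups with 5 and 7 factors were close at the earlier time, with a mean correlation of 0.968 across genes.

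How the cells changed with time was asked within each factor set (n = 3 and 3). The group without a time label was taken as the earlier one. From the earlier group to 12W, 5-factor cells gained AKR1B10, an aldo-keto reductase, by 4.20 ± 0.43 (adjusted p = 1.92e-05), and AKR1C3, a related steroid-converting reductase, by 2.76 ± 0.46, and lost CYP1B1, a cytochrome P450, by −2.79 ± 0.40. POSTN fell by 4.73 ± 0.84 (adjusted p = 0.00574), a call that ended without earlier replicate 3 (−4.27), and THY1 stood at −3.49 ± 0.87 (adjusted p = 0.0554), passing without earlier replicate 1 (−4.14) or without HDF iCM 4W replicate 3. Fibroblast and matrix genes fell in 3 of 35 (17 over the list alone; median −1.16, camera adjusted p = 9.64e-17; adjusted p = 0.127 with an estimated correlation). Cell cycle genes had 0 of 35 called by limma (13 fell over the list alone; median −0.83, adjusted p = 3.42e-12) and oxidative phosphorylation genes 0 of 26 (median 0.54, adjusted p = 3.41e-13), each with adjusted p = 0.155 with an estimated correlation. In all 54 genes rose and 67 fell. The total of 121 became 37 without earlier replicate 3, 56, 73 and 39 without 12W replicates 1, 2 and 3, and 186 without HDF iCM 4W replicate 3.

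With 7 factors, cells at 12W had more TECRL (4.03 ± 0.45, adjusted p = 4.06e-05), the potassium channel subunit KCNIP2 (3.19 ± 0.59), MYL3 (3.14 ± 0.47) and the stress-induced NUPR1 (3.65 ± 0.45) than earlier cells. MX1 fell by 4.26 ± 0.41 (adjusted p = 5.62e-06) and HP by 4.48 ± 0.84. Interferon genes fell in 12 of 26 (14 over the list alone; median −1.38, camera adjusted p = 4.89e-19), the 1 list of 9 called that held with an estimated correlation. Sarcomere genes rose in 4 of 30 (5 over the list alone; adjusted p = 9.19e-07; adjusted p = 0.361 with an estimated correlation), such as TRIM63, a muscle ubiquitin ligase, by 2.57 ± 0.35. Cell cycle genes fell in 3 of 35 (10 over the list alone; adjusted p = 2.38e-14; adjusted p = 0.149 with an estimated correlation). In all 60 genes rose and 167 fell. The total of 227 became 123 and 133 without earlier replicates 1 and 3, and 125 and 113 without 12W replicates 1 and 3. The interaction of time with factor set had 0 genes called by limma. Of 16387 genes, 376 had an unadjusted p under 0.05, fewer than the share of 0.05 that no effect would give. Without the 2 dermal arrays the interaction had 3 genes called, and without 12W 7-factor replicate 3 it had 1.

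What the reprogrammed cells still lacked was asked against H9 cardiomyocytes (n = 3 and 3 each). With 5 factors at the earlier time MYL3 was lower by −7.66 ± 0.47 (adjusted p = 2.61e-11), SMYD1, a muscle methyltransferase, by −6.69 ± 0.59, RYR2 by −4.44 ± 0.48, MYH7 by −5.48 ± 0.48, TBX20 by −4.92 ± 0.47 and NKX2-5 by −2.77 ± 0.22. COL1A1, COL1A2, THY1 and POSTN were still higher, by 2.13, 3.25, 3.30 and 5.55. MYL7, ACTC1, NPPA, NPPB and TNNI3 did not differ past the threshold (adjusted p = 0.937, 0.669, 0.972, 0.753 and 0.596). Errors shared by all human groups, which the 2 dermal arrays out of place can widen, leave room for differences. Equal levels are therefore not shown. Of 30 sarcomere genes 17 were lower (19 over the list alone; adjusted p = 9.76e-14; adjusted p = 0.16 with an estimated correlation), and of 18 calcium handling genes 11 and of 18 transcription factors 10 were lower, both calls that held. In all 1187 genes were higher and 858 lower. With 7 factors, MX1 and IFI44 of the interferon response were higher than in H9 cardiomyocytes by 4.76 ± 0.41 and 5.08 ± 0.49, with 15 of 26 interferon genes higher (18 over the list alone; adjusted p = 4.64e-13), and TECRL was lower by −7.84 ± 0.45; 1296 genes were higher and 827 lower.

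At 12W with 5 factors, MYL3 (−7.44 ± 0.47), SMYD1 (−6.20 ± 0.59) and RYR2 (−3.32 ± 0.48) remained lower than in H9 cardiomyocytes, and 1121 genes were higher and 909 lower. At 12W with 7 factors, MYL3 was lower by −3.97 ± 0.47 (adjusted p = 1.64e-06), RYR2 by −2.99 ± 0.48, MYH7 by −2.02 ± 0.48, TBX20 by −4.49 ± 0.47 and NKX2-5 by −2.55 ± 0.22, while CASQ2 (2.32 ± 0.68) and SLN, a regulator of the calcium pump (1.72 ± 0.49), were higher. Of 30 sarcomere genes 10 were lower (13 over the list alone; adjusted p = 3.13e-05; adjusted p = 0.504 with an estimated correlation) and of 18 transcription factors 8 (10 over the list alone; adjusted p = 1.12e-08), a call that held. Cell cycle genes were lower in 28 of 35 (29 over the list alone; median −1.91, adjusted p = 2.58e-20; adjusted p = 0.067 with an estimated correlation), such as TOP2A, a topoisomerase of dividing cells, by −3.10 ± 0.54. The fatty acid oxidation and energy list had a median of 0.21 and a mean of −0.37 (7 lower, adjusted p = 0.365). In all 818 genes were higher and 836 lower.

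On the line from H9F fibroblasts (0) to H9 cardiomyocytes (1), the mean position was 0.362 ± 0.033 (SD, n = 3) with 5 factors and 0.418 ± 0.015 with 7 factors at the earlier time, and 0.488 ± 0.014 and 0.524 ± 0.020 at 12W; fetal cardiomyocytes lay at 0.745 ± 0.033. Over cardiomyocyte-high genes the 4 positions were 0.374, 0.432, 0.445 and 0.494, and over fibroblast-high genes 0.346, 0.399, 0.548 and 0.567. The step from 5 to 7 factors was 0.0559 earlier and 0.0361 at 12W, and the step with time 0.126 with 5 and 0.106 with 7 factors. Each had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays can give (0.125 adjusted over 5 tests), so no step could pass 0.05; the earlier step had an exact p = 0.2 without the 2 dermal arrays. Of 1360 cardiomyocyte-high genes, 403, 451, 499 and 507 rose (29.6%, 33.2%, 36.7% and 37.3%) in the same order of groups, against 81.8, 99.9, 108 and 91.0 expected for independent lists. Of 1313 fibroblast-high genes, 275, 351, 524 and 541 fell (20.9%, 26.7%, 39.9% and 41.2%), against 33.4, 44.3, 69.1 and 69.9 expected. The shared fibroblast arrays gave simulated unchanged groups a mean position of 0.026 (highest 0.128) and at most 3 rises and 2 falls. The simulations used the human arrays without the 2 dermal arrays out of place. The falls became 494, 529, 792 and 826 of 1737 genes without H9F fibroblast replicate 1. They became 157 of 1301 with 5 factors without earlier replicate 1. The reference genes were chosen again in each fit, and the cause of these moves was not tested.

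**Figure D3:**
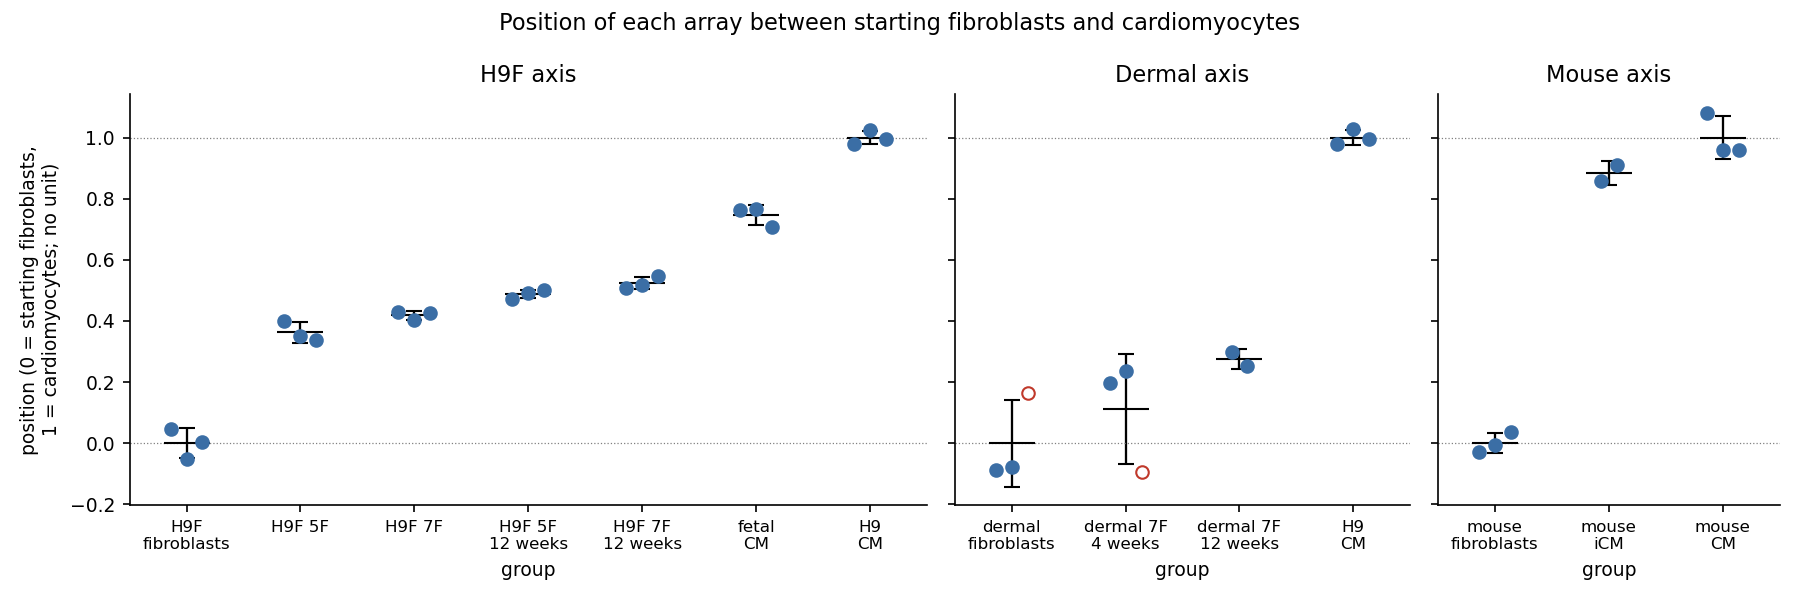
Position of each array between fibroblasts (0) and cardiomyocytes (1) by group, in panels for H9F, HDF and mouse cells, with points for arrays and bars for mean and SD. Open red points are the 2 dermal arrays that stand apart from their groups, and the mouse iCMs lie at a mean of 0.884.

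For dermal fibroblasts with 7 factors at 4W (n = 3 and 3), limma called 0 genes against HDF, with 1178 genes at an unadjusted p under 0.05. No core or delivered gene passed, MYL7 being at 3.01 ± 1.78 (adjusted p = 0.719) and MYOCD at 2.42 ± 1.69 (adjusted p = 0.756). All 25 lists had 0 members called over all genes. Camera called 9 of them, among them oxidative phosphorylation (median 0.51, adjusted p = 3.32e-13) and sarcomere genes (median 0.82, adjusted p = 4.28e-05), and 0 held with an estimated correlation (adjusted p = 0.404 for sarcomere genes). Without the 2 arrays out of place (n = 2 and 2), 1123 genes rose and 812 fell. MYL7 then rose by 9.09 ± 0.22 (adjusted p = 1.53e-18), NPPA by 8.54, ACTC1 by 8.21 and MYOCD by 7.86, all 7 delivered factors rose, and THY1 fell by 4.05 ± 0.78; COL1A1 (−1.31, adjusted p = 0.0629) and POSTN (2.25, adjusted p = 0.0609) did not pass. Sarcomere genes rose in 20 of 30 and fell in 1 (camera adjusted p = 8.09e-26), smooth muscle genes rose in 10 of 13 (adjusted p = 2.07e-14), and both calls held with an estimated correlation. Leaving out the library labelled HDF replicate 3 alone gave 531 genes, with MYL7 at 6.02 and ACTC1 at 5.35 called, and leaving out that labelled HDF iCM 4W replicate 3 alone gave 418, with MYL7 at 6.08 and MYOCD at 5.30 called.

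At 12W (n = 2, against 3 HDF arrays), 180 genes rose and 123 fell. LRRN1, a leucine-rich repeat protein gene, rose by 4.74 ± 0.76 (adjusted p = 0.00277), and among cholesterol synthesis genes HMGCS1, SQLE and MSMO1 rose by 4.19 ± 0.62, 2.17 ± 0.32 and 3.16 ± 0.45 (adjusted p = 0.00146 each). Cholesterol synthesis genes rose in 9 of 14 (12 over the list alone; median 1.46, camera adjusted p = 2.79e-19), a call that held with an estimated correlation. Sarcomere genes rose in 4 of 30 (19 over the list alone, with 1 fall; median 2.03, adjusted p = 1.84e-12; adjusted p = 0.19 with an estimated correlation). MYL7 (6.01 ± 1.99, adjusted p = 0.0989), ACTC1 (63.8-fold, adjusted p = 0.0775), NPPA (5.65 ± 1.86, adjusted p = 0.0965) and the 7 delivered factors were not called. Without the 2 arrays 1089 genes rose and 1079 fell, 301 of them among the 303 called before, and MYL7 (9.03 ± 0.22, adjusted p = 1.8e-18), MYH6 (6.26 ± 0.36) and all 7 delivered factors rose. MYL7, ACTC1, NPPA and MYOCD also passed without HDF replicate 3 alone (9.03, 8.61, 8.58 and 7.87) or HDF iCM 4W replicate 3 alone (6.01, 63.8-fold, 5.65 and 5.31). The total of 303 became 34, 33 and 1838 without HDF replicates 1, 2 and 3, 15 and 125 without 12W replicates 1 and 2, and 929 without HDF iCM 4W replicate 3.

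Between 4W and 12W 16 genes were higher and 2 lower, among them MAPT, a microtubule protein gene, by 2.25 ± 0.33 (adjusted p = 0.00841), a call that ended without 12W replicate 1 (1.76). Without the 2 arrays out of place 5 genes were higher and 9 lower, with 6 of the 18 calls shared, and MAPT was higher by 2.15 ± 0.37 (adjusted p = 0.0158). Cholesterol synthesis genes had 1 of 14 higher (6 over the list alone; adjusted p = 2.73e-16), a call that held with an estimated correlation. Without the 2 arrays it was lost with that correlation (adjusted p = 0.065). The total of 18 became 2 without 4W replicate 3 or 12W replicate 1, 74 without 4W replicate 2 and 39 without 12W replicate 2. The position between HDF and H9 cardiomyocytes was 0.113 (range −0.0944 to 0.236, n = 3) at 4W and 0.275 ± 0.032 (n = 2) at 12W (exact two-sided permutation p = 0.4, smallest possible 0.1), and 0.420 ± 0.015 and 0.462 ± 0.026 (n = 2 each) without the 2 arrays (p = 0.333 by the same exact test, its smallest). Simulated unchanged groups of 2, sharing the HDF arrays, had a mean position of 0.0288, at most 0.114. They were drawn without the 2 arrays, where HDF positions had an SD of 0.006 (n = 2), against 0.143 (n = 3) with all arrays. They therefore give no range for the positions with all arrays. Of 1331 cardiomyocyte-high genes 0 rose at 4W by limma and 74 at 12W, and of 1201 fibroblast-high genes 0 and 65 fell; without the 2 arrays 500 and 514 of 1599 rose and 550 and 664 of 1507 fell. At 4W the rises and falls became 182 of 1545 and 151 of 1439 without HDF replicate 3, and 127 of 1377 and 82 of 1264 without 4W replicate 3. At 12W they became 12 and 3, 12 and 1, and 436 and 545 (of 1545 and 1439) without HDF replicates 1, 2 and 3, and 3 and 0, and 28 and 23, without 12W replicates 1 and 2. The 4W position became 0.0557, 0.0581 and 0.278 without HDF replicates 1, 2 and 3, and 0.0712, 0.0516 and 0.230 without 4W replicates 1, 2 and 3. The 12W position became 0.189, 0.193 and 0.456 without HDF replicates 1, 2 and 3. At 12W against H9 cardiomyocytes, 931 genes were higher and 1137 lower. GDF15 and CDKN1A, a secreted stress factor and a cell cycle inhibitor, were higher by 5.70 ± 0.56 and 4.45 ± 0.39 and TECRL was lower by −8.05 ± 0.50; p53 targets were higher in 9 of 12 (adjusted p = 2.16e-10), a call that held, and cell cycle genes lower in 30 of 35 (32 over the list alone; adjusted p = 6.77e-19; adjusted p = 0.0846 with an estimated correlation).

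Mouse cardiomyocytes differed from mouse cardiac fibroblasts (n = 3 and 3) in 421 higher and 301 lower genes. Tnnt2, cardiac troponin T, was higher by 5.70 ± 0.23, Myl2 by 6.39 ± 0.18 and Fabp3, a muscle fatty acid binding protein, by 6.44 ± 0.20 (adjusted p = 3.57e-06 for the last), while Myl7 was level (−0.08 ± 0.17, adjusted p = 0.919). In mouse iCMs (n = 2) against fibroblasts, Fabp3 rose by 6.43 ± 0.22 (adjusted p = 8.82e-06), Myl2 by 6.37 ± 0.20, Actc1 by 5.99 ± 0.18, Tnnt2 by 5.30 ± 0.26, Myh6 by 4.74 ± 0.28 and Ryr2 by 4.47 ± 0.29. Timp1, an inhibitor of matrix proteases, fell by 5.81 ± 0.19, Fn1, fibronectin, by 5.26 ± 0.37 and Col1a1 by 2.87 ± 0.30. Nppa rose by 4.56 ± 0.82, a call that ended without any single array of the compared groups (4.16 to 4.97), and Myh7 (2.41 ± 0.52, adjusted p = 0.056), Postn (−1.69 ± 1.01, adjusted p = 0.489) and Thy1 (−1.15 ± 0.41, adjusted p = 0.225) were not called. The mouse forms of the human factors were not called either: Gata4 −0.08 (adjusted p = 0.848), Mef2c 1.18 (adjusted p = 0.129), Tbx5 0.33 (adjusted p = 0.572), Esrrg 0.77 (adjusted p = 0.138), Mesp1 −0.54 (adjusted p = 0.345), Myocd 0.59 (adjusted p = 0.33) and Zfpm2 −0.27 (adjusted p = 0.555). In all 264 genes rose and 247 fell; the total of 511 became 323 and 263 without iCM replicates 1 and 2.

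Mouse sarcomere genes rose in iCMs in 20 of 33 (23 over the list alone; camera adjusted p = 1.52e-36), fatty acid oxidation and energy genes in 20 of 32 (24 over the list alone; adjusted p = 2.33e-35) and oxidative phosphorylation genes in 19 of 30 (26 over the list alone; adjusted p = 6.51e-27), and these calls held with an estimated correlation. Fibroblast and matrix genes fell in 12 of 33 (16 over the list alone; adjusted p = 1.76e-16; adjusted p = 0.0874 with an estimated correlation) and smooth muscle genes in 5 of 13 (adjusted p = 2.1e-05; 0.0592 with an estimated correlation). Against mouse cardiomyocytes, 1 gene, Gabarap of autophagy, differed (−2.22 ± 0.18, adjusted p = 0.0401), with 1137 genes at an unadjusted p under 0.05. Gabarap lost its call without any 1 of the 5 compared arrays (−2.34 to −2.16). The count became 0 without any 1 of the cardiomyocyte arrays and 9 and 8 without iCM replicates 1 and 2. Sarcomere and fatty acid lists were lower than in cardiomyocytes (medians −0.33 and −0.41, camera adjusted p = 1.03e-07 each; adjusted p = 0.597 each with an estimated correlation), with 0 members called by limma. The mean position of the iCMs was 0.884 ± 0.038 (SD, n = 2). Of 421 cardiomyocyte-high genes 209 rose (49.6%, against 5.60 expected) and of 301 fibroblast-high genes 193 fell (64.1%, against 3.75 expected); the rises became 96 of 354 without iCM replicate 2 and the falls 84 and 89 of 239 without iCM replicates 1 and 2. Simulated unchanged mouse groups had a mean position of 0.0523 but reached 0.336, and 100 simulations had a median of 0 rises and 0 falls by limma, with highest counts of 459 and 259. Each simulation chose its own reference genes. These highest counts exceed the 209 and 193 observed, so the counts alone cannot exclude what unchanged groups give in these simulations. The residuals of whole arrays were drawn with replacement from the 8 arrays, so a group could hold the same residuals more than once. Such draws narrow the spread within a group. Whether they or the shared fibroblast arrays gave the highest counts was not tested. The observed position of 0.884 lay above every simulated one.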

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

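The test for a mixture in the 2 dermal arrays, the test for leukocytes and the alternative that leaves out the 2 dermal arrays were chosen after the results they measure were seen.

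The change at 12W with 7 factors differed between cell sources by a test of the difference itself, with HDF against H9F cells (n = 2 and 3 iCM arrays, 3 and 3 fibroblast arrays). The inflammatory alarm gene IL33 changed by 6.03 ± 0.91 more in HDF (adjusted p = 0.00152) and EFEMP1, a matrix gene, by 5.01 ± 0.74 more. The muscle gene CSRP3 changed by −6.11 ± 0.91 (adjusted p = 0.00152), MOXD1, a copper-dependent oxygenase gene, by −4.98 ± 0.39 (adjusted p = 7.99e-08), and TNNI1 by −4.17 ± 0.67 relative to H9F cells. By limma 108 genes differed, 51 higher and 57 lower. The count became 279 and 226 without H9F fibroblast replicates 1 and 3, 63 without HDF replicate 1, 167 without HDF iCM 4W replicate 3, 62 without H9F iCM 12W 7-factor replicate 3, and 29 and 70 without HDF iCM 12W replicates 1 and 2. It was 436 without the 2 dermal arrays out of place, with IL33 at 6.52 ± 0.74, CSRP3 at −4.98 ± 0.45 and MOXD1 at −4.90 ± 0.41.

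By gene list, camera called this difference for 4 lists, and 0 of these calls held with an estimated correlation (adjusted p = 0.756 for each). Among them were sarcomere (median −1.82, 3 of 30 lower, 10 over the list alone; camera adjusted p = 1.396e-10) and fibroblast and matrix genes (median 1.08, 3 of 35 higher, 8 over the list alone; adjusted p = 7.787e-06). Also, fatty acid oxidation and energy genes had a median of −0.70 (adjusted p = 0.001979) and oxidative phosphorylation genes a median of −0.45 (adjusted p = 1.244e-05). Without the 2 dermal arrays out of place the medians were −0.70 for sarcomere (adjusted p = 0.000458), 0.46 for fibroblast and matrix (adjusted p = 0.03), −0.07 for fatty acid oxidation and energy (adjusted p = 0.679) and −0.21 for oxidative phosphorylation (adjusted p = 0.121). The last 2 lists were then no longer called.

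The change with time differed between 7 and 5 factors in 4 gene lists (n = 3 in each of 4 groups), again by a test of the difference. The interferon list had a median of −0.99 (camera adjusted p = 1.4e-18, 8 of 26 lower over the list alone), a call that held with an estimated correlation (adjusted p = 0.000176). Fibroblast and matrix genes (median 0.67, adjusted p = 2.156e-07) and inflammatory secretion genes (0.34, adjusted p = 0.0009439) had adjusted p = 0.45 with an estimated correlation, and smooth muscle genes (0.45, adjusted p = 0.0392) 0.987. No single gene was called by limma. Of 16387 genes, 376 had an unadjusted p under 0.05, again below the share that no effect would give. A real count of 0 is reached by every split, so the 100 of 100 drawn splits that gave as many say nothing about chance; the highest other split gave 892.

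Interferon genes such as MX1 and OAS1 were higher with 7 than with 5 factors at the earlier time, with a list median of 0.98. The mean over the list was 5.19 to 5.22 in the 5-factor arrays, 6.05 to 6.31 in the 7-factor arrays and 4.74 to 5.02 in H9F fibroblasts. A single array did not carry the difference, whose lowest median was 0.744, without 7-factor replicate 2. Quantile normalization left 0.913, but the medians of these arrays already lay close together. It could therefore test little of the scaling between arrays. Leukocyte markers were not higher with 7 factors, with a median of −0.193 (SD 0.405). CD68 and TYROBP, the markers with the highest signals, were at 5.42 and 5.38 against 6.41 and 5.73. Signals this near the array medians of 5.31 to 5.34 may not reveal a small share of leukocytes, which stays open. The added factors, a difference in virus and a difference in time since infection stay open as untested candidate explanations.

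The 2 dermal arrays out of place may have had their labels exchanged. Across the 7 delivered factors the library labelled HDF replicate 3 had a median of 2.94 above the other HDF arrays, and the library labelled HDF iCM 4W replicate 3 one of −3.46 from the other arrays of its group, which an exchange needs. Over 1928 genes that separate the other arrays, their positions were 0.920 and 0.0508 on a scale from HDF (0) to 4W iCMs (1). The low value argues against a mixture in the library labelled HDF iCM 4W replicate 3. A mixture is not linear on log2 values, so 0.920 cannot exclude a share of fibroblasts in the library labelled HDF replicate 3. An exchange was found from these values and is a hypothesis. Beyond the splits of the arrays given below, among which is the exchanged labelling, no fit with exchanged labels was made. No biological explanation was tested.

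The mouse iCMs lay close to mouse cardiomyocytes, with Myl2, Actc1 and Fabp3 near the cardiomyocyte level. Quantile normalization left the mean position at 0.895. The array medians of the deposited RMA values already lay close together, so it could test little of the scaling between arrays. Cardiomyocytes carried over into the sort, with the rest fibroblasts, would give the same share from both kinds of genes. The shares were 0.581 from cardiomyocyte-high and 0.995 from fibroblast-high genes in replicate 1, and 0.820 and 0.975 in replicate 2, with a larger difference of 0.413. Carry-over and reprogramming cannot be told apart, since an array scale may compress high signals and the cells other than cardiomyocytes need not be fibroblasts.

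The 10 splits of 3 against 3 arrays are too few for a share under 0.05. Real counts and the highest of the other splits were 2677 and 111 for H9 cardiomyocytes against H9F fibroblasts, 2885 and 53 for fetal cardiomyocytes against them, 1434 and 3 between the cardiomyocytes, and 682 and 445 between HDF and H9F fibroblasts. For H9F iCMs against fibroblasts they were 1403 and 74 (5 factors), 1757 and 26 (7 factors), 2159 and 3 (5 factors, 12W) and 1968 and 21 (7 factors, 12W). Against H9 cardiomyocytes they were 2045 and 3, 2123 and 1, 2030 and 2, and 1654 and 1 in the same order. Over time they were 121 and 1 with 5 factors and 227 and 1 with 7, and for mouse cardiomyocytes against fibroblasts 722 and 0. In each of these, 1 split, the real one, gave as many genes. The same held for 7 against 5 factors at the earlier time (16 and 6), whereas at 12W 2 of the 10 splits gave as many (5 and 8). For HDF iCMs at 4W against HDF the real count of 0 is reached by all 10 splits, which says nothing about chance. Another split gave 2096, which points to a structure of the samples other than their labels. The exchanged labelling is among the other splits, but which split gave 2096 was not recorded.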

How the results depend on the processing

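The alternative that leaves out the 2 dermal arrays out of place was chosen after the data were seen. The others were planned. Position differences kept their direction in all 59 leave-one-out fits and in 5 of 5 cases under each other alternative. The exact test, which cannot pass 0.05 in this design, was repeated only without the 2 dermal arrays. Counts of genes stayed within 1.5 times the main count in 23 of 25 comparisons with quantile normalization, 24 with median centring, 24 with trend and robust variance, 24 with every row of the table, 20 without dim genes, 19 with a replicate block, 14 with array weights, 13 with only the compared arrays, 14 of 22 without the 2 dermal arrays and 132 of 176 leave-one-out fits.

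Without the 2 dermal arrays the counts were 46 (7 against 5 factors), 42 (the same at 12W), 319 and 401 (12W against earlier with 5 and 7 factors), 1935 and 2168 (HDF iCMs at 4W and 12W against HDF), 3 (time by factors) and 436 (HDF against H9F). The HDF iCM positions were 0.420 (4W) and 0.462 (12W), with 500 and 514 reference genes risen and 550 and 664 fallen. Reversed lists had adjusted p = 0.789 (delivered factors, HDF iCMs 12W against 4W), 0.702 (sarcomere, HDF against H9F fibroblasts) and 0.0241 (smooth muscle, HDF against H9F difference). These arrays widen the errors that all groups share, as for MYOCD with 7 against 5 factors (1.69 with them, 0.58 without).

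Array weights gave 60 and 47 genes (7 against 5 factors, earlier and 12W), 474 and 538 (12W against earlier, 5 and 7 factors), 1128 (HDF against H9F fibroblasts), 2028 and 2316 (HDF iCMs at 4W and 12W), 66 (12W against 4W), 6 (mouse iCMs against cardiomyocytes), 4 (time by factors) and 794 (HDF against H9F difference); the cause was not tested.

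With only the compared arrays, which leaves fewer samples to estimate errors, counts were 1783 (H9 cardiomyocytes against H9F fibroblasts), 64 (HDF against H9F fibroblasts), 788, 1051 and 1231 (5 factors, 7 factors and 7 factors at 12W against fibroblasts), 19 (7 against 5 factors at 12W), 352 and 381 (over time), 10 (HDF against H9F difference), and, by limma, 0 for HDF iCMs at 12W against HDF and against 4W and for mouse iCMs against cardiomyocytes.

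Without dim genes, so with fewer tested, counts were 797 (H9 against fetal cardiomyocytes), 5 (7 against 5 factors), 68 and 144 (over time) and 3 (HDF iCMs 12W against 4W). Positions were 0.402, 0.468, 0.544 and 0.581 for 5 and 7 factors earlier and at 12W, and 0.309 for HDF iCMs at 12W, and 233 of 1031 reference genes fell with 7 factors. With a fetal end the first 4 positions were 0.317, 0.357, 0.406 and 0.441. With the other fibroblasts as the end they were 0.446 and 0.483 at 12W, and 0.290 and 0.447 for HDF iCMs at 4W and 12W.

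The human fits with a replicate block also left out HDF iCM 4W replicate 3, so their values cannot be credited to the block alone. They gave 12 genes (7 against 5 factors at 12W), 506 and 992 (HDF iCMs at 4W and 12W) and 1 (12W against 4W). In mouse the block gave 287 genes (iCMs against fibroblasts) and 0 by limma (against cardiomyocytes). With the block, reference genes risen and fallen were 146 and 92 (4W), 213 and 243 (12W) and 131 and 110 (mouse). At 4W, leaving out only HDF iCM 4W replicate 3, with no block, gave 127 risen and 82 fallen. With the block the delivered factors reversed for HDF iCMs 12W against 4W (camera adjusted p = 0.909). Quantile normalization gave 12 genes for 7 against 5 factors at 12W. For mouse iCMs against cardiomyocytes quantile normalization, median centring and trend and robust variance each gave 0 by limma (1 in the main count), and every row gave 10. The cause was not tested.

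Leaving out 1 array at a time moved counts from 2 (without 7-factor replicate 3) to 19 (7 against 5 factors), from 3 to 25 (without 12W 7-factor replicate 2) at 12W, from 37 (without earlier replicate 3) to 186 with 5 factors over time, and from 113 (without 12W replicate 3) to 279 with 7. The values 19, 186 and 279 were without HDF iCM 4W replicate 3. For HDF iCMs they moved from 0 to 531 (without HDF replicate 3) at 4W, 15 (without 12W replicate 1) to 1838 (without HDF replicate 3) at 12W, and 2 to 74 between the times (without 4W replicates 3 and 2). Mouse iCM counts moved from 263 (without iCM replicate 2) to 548 (without fibroblast replicate 3) against fibroblasts and 0 to 9 (without iCM replicate 1) against cardiomyocytes. Time by factors moved from 0 to 1, and HDF against H9F from 29 to 279.

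Positions moved from 0.344 to 0.409 (0.4085), 0.405 to 0.458, 0.467 to 0.528 and 0.503 to 0.564 for the 4 H9F iCM groups in the same order, each highest without H9F fibroblast replicate 1, from 0.0516 (without 4W replicate 2) to 0.278 (without HDF replicate 3) for HDF iCMs at 4W, 0.189 to 0.456 at 12W and 0.832 to 0.916 for mouse iCMs. Reference genes fallen moved from 157 to 494, 247 to 529, 414 to 792 and 438 to 826 in the H9F groups, 0 to 151 and 0 to 545 in HDF iCMs at 4W and 12W and 84 to 249 in mouse iCMs. Those risen moved from 0 to 182, 3 to 436 and 96 to 210 in the last 3. The cause was not tested.

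Of 244 gene list calls 59 were kept with an estimated correlation (185 lost), 235 with quantile normalization, 232 with the block, and 195 of 215 without the 2 dermal arrays. Of 1138 calls of named genes, 1107 were kept with quantile normalization, 870 with only the compared arrays (92 calls gained), 1093 with the block (198 gained) and 1008 of 1015 without the 2 arrays (495 gained). Leave-one-out fits kept 6649 of 7730 such calls and gained 423. Another background correction and a block for slide could not be tried from the deposited value tables, which also set what signal over background can be judged.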

Other observations

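The steroid-enzyme genes and GNG8 below were chosen after their values were seen. HSD3B2, a steroid dehydrogenase of the adrenal and gonad, was among the largest rises in every H9F iCM group against H9F fibroblasts, by 8.25 ± 1.00 (adjusted p = 7.76e-06), 8.32, 7.63 and 7.30 for 5 and 7 factors earlier and at 12W (n = 3 each). In H9 cardiomyocytes it was at 0.42 (adjusted p = 0.845). HSD3B1, its close relative, rose by 3.06, 2.88, 4.13 and 2.90. CYP17A1, a steroid hydroxylase, was at 0.87 (adjusted p = 0.388) with 5 factors and rose by 2.44, 3.67 and 2.58 in the others. CYP19A1, which makes estrogens, rose by 3.74, 3.16 and 4.22 and was at 2.08 (adjusted p = 0.113) with 7 factors at 12W. SULT2A1, a steroid sulfotransferase, rose by 4.03, 6.33 and 5.35 and was at 2.17 (adjusted p = 0.298) with 7 factors at the earlier time. Without the 2 dermal arrays out of place these CYP19A1 and SULT2A1 changes passed (adjusted p = 0.004032 and 0.01952 by limma). CYP17A1 with 5 factors did not (adjusted p = 0.1065). CYP11A1 and STAR, which act at the start of steroid synthesis, and NR5A1, a regulator of steroid genes, were not called in any of these groups. In HDF iCMs none of these 8 genes was called against HDF, with HSD3B2 at 1.20 (adjusted p = 0.793) at 4W and 3.55 (adjusted p = 0.085) at 12W. Without the 2 dermal arrays out of place HSD3B2 rose by 4.36 and 5.14, and HSD3B1, CYP17A1, CYP19A1 and SULT2A1 were also called at both times. HSD3B1 and HSD3B2 are near-identical in sequence, so probes shared by the pair cannot assign the signal to either.

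GNG8, a G protein subunit gene, rose by 6.63, 7.00, 7.48 and 6.54 in the same groups, and in H9 cardiomyocytes it was at 1.19 (adjusted p = 0.572). The liver gene AFP was 7.89 ± 4.70 (SD, n = 3) in H9 cardiomyocytes against 2.40 in fetal cardiomyocytes. HBB was 9.93 ± 1.02 (SD, n = 3) in fetal cardiomyocytes against 4.09 ± 0.17 in H9F fibroblasts.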
